A study of Homo sapiens with 28 samples.

How the data were processed

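Chromatin immunoprecipitation sequencing (ChIP-seq) of 2 marks on lysine 27 of histone H3 was analysed: the acetylation H3K27ac, found at active promoters and enhancers, and the trimethylation H3K27me3, which the Polycomb enzyme EZH2 writes at silenced genes. The mouse samples were bone marrow of 3 WT mice (floxed Ezh2 and Runx1 alleles, no Cre, normal Flt3) and of 5 DKOITD mice, which carried the same floxed alleles with a Rag1-driven Cre and an internal tandem duplication of Flt3. Per the labels, WT marrow was enriched for Kit-expressing cells on CD117 beads and DKOITD marrow was used whole, so cell preparation went with genotype in every comparison of mice. The human samples were the T-cell leukaemia lines Jurkat and Loucy, with 2 libraries per line and mark. Of 28 libraries, 24 had peak lists, and the 4 input libraries were used here only as the controls named in the file headers.

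Per the labels' protocols, cells were fixed in 1% formaldehyde for 10 min and the chromatin was sheared to 200 to 500 bp. Drosophila chromatin was added at 1 cell to 4 sample cells, and the labels state that its reads were not used by the submitters. The peak lists therefore carry no absolute level of either mark. Per the submitters' processing notes, the tools were Bowtie2 2.2.5 and MACS2 2.0.10 and the builds were mm10 and hg38. Per the file headers, the authors called broad peaks with MACS 2.0.10.20131216 on paired fragments, separately for each library, at a q cutoff of 0.05, keeping 1 fragment per position. Per the file headers, all WT libraries were called against the input of WT1, all DKOITD libraries against that of DKOITD48, and each cell line against the input of its replicate 2. The headers of the H3K27ac libraries WT1 and DKOITD53e name the alignments of a single run, and the others name merged alignments.

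Per the file headers, each peak has a pileup, which is the signal (fragment coverage) averaged over the peak. The authors' files also give the −log10 of its p-value and of its q-value, both computed by MACS. The fold enrichment deposited by the authors is the ratio of that signal to the local background. These values are the authors' own for each peak and served only to rank or filter peaks within a list. Because depth and enrichment differed, libraries were compared by presence and extent of peaks. The headers give the fragments left after duplicate removal: 2766339 to 6411696 for mouse H3K27me3, 6515614 to 11458360 for mouse H3K27ac, 3900279 to 12261421 for human H3K27me3 and 11329731 to 12521211 for human H3K27ac. Weak or narrow peaks are the first to be missed at low depth or enrichment, so the absence of a peak is not absence of the mark. The percent of fragments in peaks was estimated as pileup times peak length, summed and divided by fragment size and by the number of fragments.

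Overlapping peaks of a library were merged, and territory is the length of genome under them. Gene positions came from a RefSeq table of the mouse assembly GRCm38, the assembly behind mm10, with 21883 protein-coding genes used. The table gives no strand, so the planned promoter window was replaced by windows of 1 kb either side of both gene ends. This departure was set after the table was seen and before any gene was counted. A gene was marked in a library when peaks covered at least 200 bp of its better covered window, and the mark can therefore lie at the 3' end. A gene lost a mark when all 3 WT libraries and no DKOITD library were marked, and gained it in the opposite case. Regions were the merged peaks of all 8 libraries, held by a library whose peaks covered at least 10% of the region. No human annotation was used here, so human results are given as regions, and the planned comparison of mouse with human genes was not run.

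Territories, mark ratios, list shares and promoter states were compared by two-sided exact permutation tests of the difference of means, over 56 assignments of the mice, where the smallest possible p is 0.0357. Promoter states keep their planned name but were counted in the windows at both gene ends. For 2 against 2 cell line libraries the smallest possible p is 0.333. The Jaccard index, shared length over joint length, was averaged within and between genotypes and tested one-sided over the same assignments. Counts of switched genes and regions were set against all 56 splits of the 8 libraries. The lists, 23 in number with 389 symbols, were fixed before the data were examined, and 2 symbols had no gene in the table. A list's share of marked genes was taken minus that of all genes in the same library, with Benjamini-Hochberg adjustment over the 23 lists. At least 17 lists at the smallest p would be needed for any to pass, so this adjusted test could hardly detect a single list. Fisher's exact test across genes was used for the relation of the 2 marks and for lists among switched genes, with genes that could have switched as background. Genes are not independent replicates.

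limma 3.58.1 in R 4.3.3 was run on the covered fraction of the gene windows as an alternative, with its camera test for lists. The other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. The scripts were tested on simulated data with 200 lost and 200 gained genes per mark. The switch rule recovered 200 of 200 in each direction for both marks in both simulations, among 205 to 223 genes called per direction. Changed genes were simulated so as to meet the rule, so this recovery was fixed in advance. The simulated libraries lacked the differences in peak number between real libraries, so the surplus calls do not give the real error. limma recovered 200 of 200, among 214 to 235 called, where changed genes had 1 level with little spread, and 0 where each library's covered length was drawn independently. A limma count of 0 is therefore weak evidence of no change.

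Genes are named by a rule fixed before the data were examined, except that both gene ends replaced the planned most upstream start site. It takes the 10 switched genes per mark and direction with the largest difference in covered length within 5 kb of a gene end. It adds members of the lists that switched, and Ezh2, Runx1, Flt3, Rag1 and Kit. Where fewer than 5 genes switched, those with the largest difference in the share of libraries marked were taken. Predicted genes and members of near-identical families were counted and not named. Alternatives fixed beforehand were peaks with a −log10 q of at least 5, other minimum overlaps, windows of 2.5 kb, peaks of at least 1000 bp, the same number of strongest peaks in every library, limma, and leaving out each library. Alternatives chosen after seeing the data were whole genes plus 1 kb, leaving out chromosomes X and Y, leaving out DKOITD48, DKOITD53e and DKOITD83, leaving out stretches called in every library, camera, an unadjusted threshold for lists, the exchange of marks with stricter peaks, and the human region counts.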

Results

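The data are peak lists of H3K27me3 and H3K27ac in the marrow of 3 WT and 5 DKOITD mice, and in 2 libraries each of Jurkat and Loucy cells. Jurkat is a T-cell acute lymphoblastic leukaemia line, and Loucy is a T-cell leukaemia line used as a model of early T-cell precursor disease. The series title places the study in the joint action of Ezh2 and Runx1 mutations in leukaemia arising from early thymic progenitors. The DKOITD mice are labelled DKOITD48, DKOITD52, DKOITD53e, DKOITD83 and DKOITD185. Mouse libraries held 2766339 to 6411696 fragments for H3K27me3 and 6515614 to 11458360 for H3K27ac. WT marrow was enriched for Kit-expressing cells and DKOITD marrow was not, so genotype and cell preparation differ together in all mouse comparisons. Sex also nearly followed genotype. H3K27ac lay over none of the 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty in the 3 WT mice and DKOITD83, and over 3 or 4 of them in the other 4 DKOITD mice.

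At the engineered genes, Ezh2 (mm10 chromosome 6, 47530274 to 47595270) and Runx1 (chromosome 16, 92601466 to 92826074) carried H3K27ac in 3 of 3 WT and 5 of 5 DKOITD mice and H3K27me3 in none. Rag1, whose product cuts antigen receptor genes, carried neither mark in any mouse. Flt3, a cytokine receptor of progenitors, carried H3K27me3 in 3 of 3 WT mice and 1 of 5 DKOITD mice, and H3K27ac in 2 of 3 and 5 of 5. Peaks at the ends of a gene do not show whether a floxed exon was deleted, so these values do not check the genotypes.

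The first comparison asked how much of the genome each mark occupied. H3K27me3 peaks covered 20.9 Mb ± 6.74 (SD, n = 3) in WT and 16.9 Mb ± 17.3 (SD, n = 5) in DKOITD marrow, a difference smaller than the spread between mice (exact permutation p = 0.75). H3K27ac peaks covered 22.6 Mb ± 6.59 (SD, n = 3) and 14.3 Mb ± 7.56 (SD, n = 5), with an exact permutation p of 0.179. The difference in mouse H3K27ac territory, -8.21 Mb, shrank to -3 Mb with peaks of −log10 q at least 5 and to -3.70 Mb at equal peak numbers. The DKOITD mice differed widely from each other. H3K27me3 covered 40.5 Mb in DKOITD185 and 30.3 Mb in DKOITD52, against 5.20 Mb in DKOITD48, 3.17 Mb in DKOITD53e and 5.24 Mb in DKOITD83. For H3K27ac the same 3 mice had 13.1, 7.03 and 7.46 Mb, the smallest territories of the 8. Their fragments lay in H3K27ac peaks in 11.3%, 6.09% and 6.40% of cases, against 14.2% to 27.2% in the other 5 mice. With peaks of −log10 q at least 5, the difference in mouse H3K27me3 territory changed sign, to 3.88 Mb more in DKOITD marrow, with an exact permutation p of 0.464. That setting left only 95 to 814 H3K27me3 peaks per WT mouse and 184 to 2015 per DKOITD mouse.

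**Figure D1:**
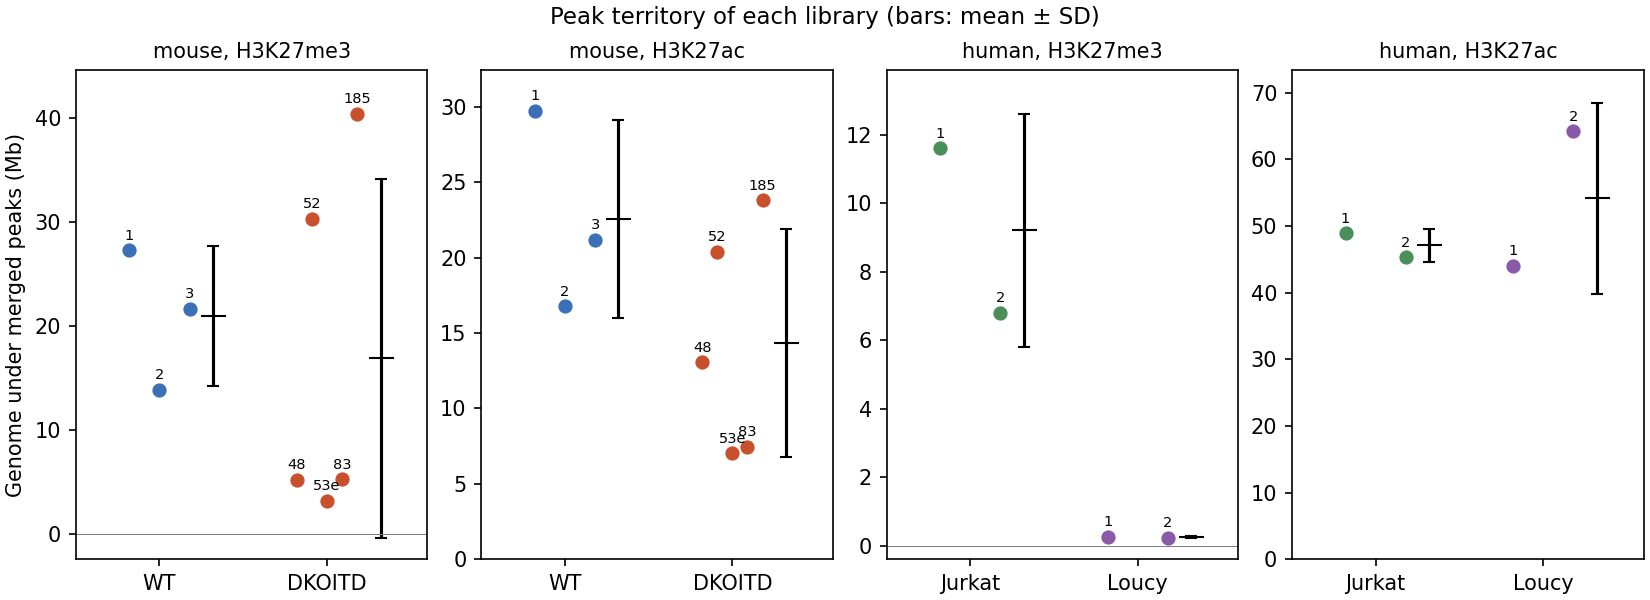
Genome length under merged peaks (Mb, vertical axis) for each library, by mark and organism, with replicate names beside the points and black bars for the group mean ± SD. In mice the H3K27me3 points of DKOITD48, DKOITD53e and DKOITD83 lie at 3.17 to 5.24 Mb and those of DKOITD52 and DKOITD185 at 30.3 and 40.5 Mb, and in the cell lines H3K27me3 covers 6.80 to 11.6 Mb in Jurkat and under 0.3 Mb in Loucy.

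Genes that lost H3K27ac in DKOITD marrow included Kit, the stem cell factor receptor, Camp, S100a8 and Car2, a carbonic anhydrase of red cells. Camp, an antimicrobial peptide of neutrophils, had 3.52 kb ± 0.549 (SD, n = 3) covered within 5 kb of a gene end in WT and 0 in DKOITD. S100a8, a calcium-binding protein abundant in neutrophils, had 3.58 kb ± 1.21 (SD, n = 3) and 0. Kit (chromosome 5, 75574987 to 75656722) had 1.5 kb ± 0.424 (SD, n = 3) and 0. WT marrow was selected on Kit itself, so its loss cannot be told apart from cell preparation. In all, 101 of 21883 genes were marked in 3 of 3 WT and 0 of 5 DKOITD mice. Those with the largest differences were Wfdc21, Itgb2l, Pxylp1, Rasgef1c, Syne1, Pde6h, C5ar2, S100a8, Camp and G0s2. List members among them were Kit, Fli1 and Mllt3 of the stem and progenitor list, Camp and S100a8 of the granulocyte and monocyte list, and Car2 and Sptb of the erythroid list. Kit is also on the mast cell list. Sptb shares a window with Plekhg3 and Wfdc21 with Heatr6, so those peaks cannot be assigned to a single gene. Counted over the whole gene plus 1 kb, Fli1 and Pxylp1 carried H3K27ac in 5 of 5 DKOITD mice, Syne1 in 4, Sptb in 3, and Kit and Mllt3 in 1 each.

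By Fisher's exact test among the 8463 genes marked in all WT mice, the stem and progenitor list held 3 of the lost genes where 0.0835 were expected (adjusted p = 0.00128). Kit, on which WT marrow was selected, was among the 3, so this excess cannot be told apart from cell preparation. By camera that list did not pass, with an adjusted p of 0.218 with the preset correlation and an adjusted p of 0.891 with an estimated correlation. The erythroid list held 2 where 0.0477 were expected (adjusted p = 0.00958), and its camera call was lost, at an adjusted p of 0.293, with an estimated correlation. The granulocyte and monocyte list held 2 where 0.203 were expected, with an adjusted p of 0.0981, which missed the threshold. limma called 186 genes lower and 61 higher in DKOITD at an adjusted p under 0.05, including 79 of the 101 lost genes. Among those named, Fli1 (limma adjusted p = 0.0802), Mllt3 (0.0739) and G0s2 (0.102) missed limma's threshold, the first 2 being members of the stem and progenitor list. When every library was reduced to its 8825 strongest peaks, 86 genes met the rule of loss and only 13 of the 101 were among them. S100a8, Pxylp1, Pde6h and Fli1 were among the 13, and Kit, Mllt3, Camp, Car2 and Sptb were not. Neither lost gene of the erythroid list was thus kept. With peaks of −log10 q at least 5, 28 genes lost the mark, 4 of the 101 among them, and 65 gained it. The count of 101 was 178 without WT2 and 165 without DKOITD52.

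The genes with the largest gains of H3K27ac in DKOITD marrow included H2-Ab1, H2-Aa and Cd74. The first 2 encode chains of major histocompatibility complex class II molecules, which no fixed list covered, and no list passed Fisher's exact test among the gained genes. H2-Ab1 had 0.440 kb ± 0.403 (SD, n = 3) covered in WT and 5.91 kb ± 0.829 (SD, n = 5) in DKOITD marrow. Cd74, the invariant chain that escorts class II molecules, had 0.208 kb ± 0.360 (SD, n = 3) and 5.02 kb ± 0.676 (SD, n = 5). H2-Aa had 0 and 4.49 kb ± 1.71 (SD, n = 5). limma's adjusted p was 9.56e-05 for H2-Ab1, 9.56e-05 for Cd74 and 0.00917 for H2-Aa, and 43 of the 82 gained genes were called by limma. In all, 82 genes were marked in 0 of 3 WT and 5 of 5 DKOITD mice. Every WT H3K27ac library held fewer fragments than any DKOITD library, so depth cannot be told apart from genotype in these gains. Others with large differences were Irf5, Prss30, Nrp1, Rasa4, Metrnl and Slc35e4, and Batf3, a transcription factor of dendritic cells, was the list member. Of these, Irf5 (limma adjusted p = 0.0700), Prss30 (0.126), Nrp1 (0.104) and Batf3 (0.0989) missed limma's threshold. Counted over the whole gene plus 1 kb, Nrp1 carried H3K27ac in 3 of 3 WT mice, H2-Ab1 in 2, and Cd74, Irf5 and Metrnl in 1 each, which ended these 5 calls. Cd74 shares a window with Tcof1, and Irf5 with Tnpo3. At equal peak numbers 183 genes met the rule of gain, 38 of the 82 among them, and with the stricter peaks 65 did, 7 of the 82 among them. The count was 373 without DKOITD48, DKOITD53e and DKOITD83 together, 129 without WT1 and 130 without DKOITD53e.

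H3K27me3 was lost at 67 genes, among them Irf8 and Irf5, interferon regulatory factors of myeloid and dendritic cells. Irf8 (chromosome 8, 120736358 to 120756694) had 2.35 kb ± 0.478 (SD, n = 3) covered in WT and 0 in DKOITD marrow. Irf5 had 2.76 kb ± 0.237 (SD, n = 3) and 0. Others with the largest differences were Map4k4, Nrp1, Arhgap12, Tpm4, Tsc22d1, Prag1, Emilin2 and Rnd3. Counted over the whole gene plus 1 kb, Arhgap12 carried H3K27me3 in 1 DKOITD mouse, which ended its call. These losses were from all 5 DKOITD mice, including DKOITD52 and DKOITD185, whose H3K27me3 territories exceeded those of every WT mouse. By the same rule Cd81 and Dusp6 gained H3K27me3. Dusp6, a phosphatase that restrains ERK, had 0 in WT and 1.37 kb ± 0.529 (SD, n = 5) in DKOITD marrow. Cd81 had 0 and 2.59 kb ± 1.85 (SD, n = 5), in a window shared with Tssc4. Next by the share of mice marked, without meeting the rule, were Pip5k1b, Spry2, Tuba8, Cd24a and S1pr1, with Bhmg1, Vegfa and F12 after them. Spry2, another antagonist of ERK signalling, was marked in 0 of 3 WT and 4 of 5 DKOITD mice. limma called 0 genes for H3K27me3 at an adjusted p under 0.05 and 423 lower and 7 higher at an unadjusted p under 0.05. At equal peak numbers 37 genes lost the mark, only 3 of the 67 among them, and with peaks of −log10 q at least 5 the count was 0. Gains then numbered 22 and 16, with neither Cd81 nor Dusp6 among them. The stricter setting left 265, 95 and 814 H3K27me3 peaks in WT1, WT2 and WT3, and equal peak numbers left 1891 per mouse. The excess of losses over gains was not kept with the stricter peaks, but few losses could be counted among so few WT peaks. Without DKOITD48, DKOITD53e and DKOITD83 together 198 genes gained the mark. The count of losses was 189 without WT2 and 182 without DKOITD52, and that of gains was 4 without DKOITD83.

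**Figure D2:**
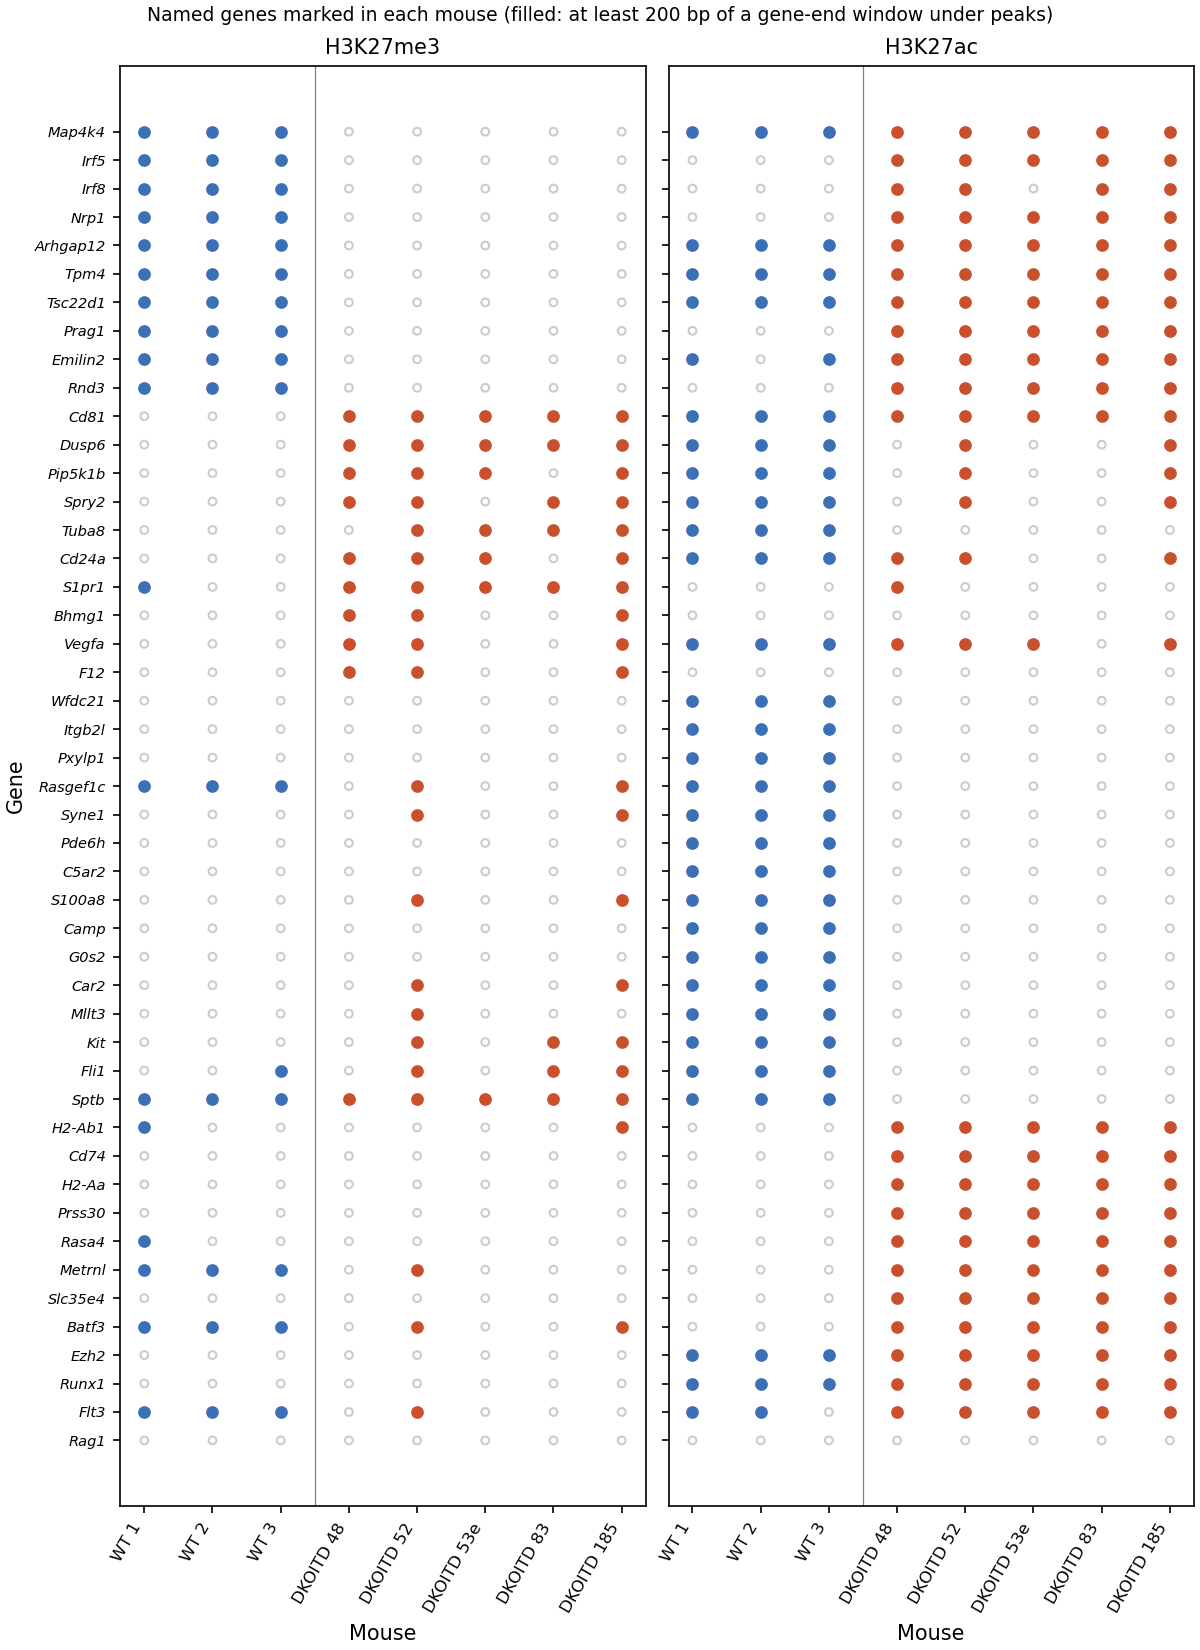
Marks at the named genes (rows) in each of the 8 mice (columns), with H3K27me3 left and H3K27ac right, where filled points are mice in which peaks covered at least 200 bp of a gene-end window, open points are mice in which they did not, and colour gives the genotype. Irf5, Nrp1, Prag1 and Rnd3 are filled for H3K27me3 in the 3 WT mice only and for H3K27ac in the 5 DKOITD mice only.

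Both marks modify the same lysine, so their switches were compared gene by gene. At 11 genes H3K27me3 was lost and H3K27ac gained: Irf5, Nrp1, Rnd3, Prag1, Capn2, Niban2, Lrfn1, Ccdc102a, Stxbp6, Bin1 and Apba1. Of these, Capn2, Niban2, Lrfn1, Ccdc102a, Stxbp6, Bin1 and Apba1 fall outside the naming rule and were chosen after their values were seen. The better covered gene end was taken for each mark and library, so the marks can lie at opposite ends of a gene. An exchange at a single site was not tested. Over the whole gene plus 1 kb, Nrp1 carried H3K27ac in 3 of 3 WT mice as well. Among 2725 genes with H3K27me3 in all WT mice and H3K27ac in none, 30.6% of genes that lost H3K27me3 gained H3K27ac, against 1.23% of the rest (Fisher's exact test, p = 2.30e-12). The expected number was 0.581. Irf8 lost H3K27me3 and carried H3K27ac in 4 of 5 DKOITD mice, missing the rule by 1 mouse. The opposite exchange occurred at 0 genes, where only 0.0192 were expected, so its absence carries no weight. The count of 11 became 2 at equal peak numbers and 0 with peaks of −log10 q at least 5. With those stricter peaks no gene lost H3K27me3, so no exchange could be counted.

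Peak regions across the genome were compared in the same way. H3K27ac was lost from 1117 of 32836 regions and gained at 162. The excess of losses was not kept with peaks of −log10 q at least 5, with 83 lost and 84 gained, and was smaller at equal peak numbers, with 358 and 291. Without DKOITD48, DKOITD53e and DKOITD83 together 1865 were gained. Only 11.3% of the lost regions touched a gene-end window, against 53.7% of the gained and 85.5% of the 6521 regions held in every mouse. The longest lost regions lay within 1 kb of or inside Gsr (chromosome 8, 33658741 to 33669340), Bace1 and Prkcb. For mouse H3K27ac switched regions, lost, the count was 2329 without WT2, and for mouse H3K27ac switched regions, gained, it was 244 without WT1, 315 without DKOITD53e and 244 without DKOITD83. The longest gained region (chromosome 16, 93026009 to 93035447) had no gene within 1 kb, and the next (chromosome 8, 120735662 to 120744414) covered the start of the Irf8 interval. H3K27me3 was lost from 130 of 41384 regions and gained at 3. These counts were 0 and 16 with the stricter peaks and 57 and 19 at equal peak numbers, and 1939 were gained without the 3 mice. The longest lost regions were at Bcor, Cd40 and Rara, and those gained were at Pip5k1b, Cd81 and Dusp6. Bcor lies on chromosome X, where sex, which nearly followed genotype, cannot be told apart from it. For mouse H3K27me3 switched regions, lost in DKOITD, the count was 515 without WT2, 230 without WT3 and 290 without DKOITD52. For mouse H3K27me3 switched regions, gained, it was 8 without DKOITD53e and 5 without DKOITD83.

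The share of each fixed gene list that was marked was compared relative to all genes. H3K27ac marked 31.6% ± 5.26 (SD, n = 3) of the 19 erythroid genes in WT and 2.11% ± 2.88 (SD, n = 5) in DKOITD marrow. It marked 51.7% ± 10.4 (SD, n = 3) and 24.0% ± 8.22 (SD, n = 5) of the 20 stem and progenitor genes. For the mast cell and basophil list the shares were 13.9% ± 4.81 (SD, n = 3) and 0 in 5 DKOITD mice. For the dendritic cell list they were 30.6% ± 4.81 (SD, n = 3) and 50% ± 11.8 (SD, n = 5). These 4 lists each had an exact permutation p of 0.0357 and an adjusted p of 0.205, so none passed. limma's camera with its preset correlation called the erythroid (adjusted p = 0.00108), mast cell (adjusted p = 0.0426) and dendritic cell (adjusted p = 1.50e-04) lists. All 3 had an adjusted p of 0.293 with an estimated correlation. The mast cell call rested on only 2 tested genes, Il1rl1 and Kit. WT marrow was selected on Kit, so that call cannot be told apart from cell preparation. Adjusted over the list alone, limma called 7 of 16 tested stem and progenitor genes, against 2 adjusted over all genes. Lmo2, Mllt3, Tal1, Kit, Fli1 and Angpt1 were lower and Flt3 was higher. In the granulocyte and monocyte list it called 11 of 27 adjusted over the list alone and 6 over all genes, with Klf4 and Irf8 higher and the other 9 lower. That list was marked at 75% ± 10.7 (SD, n = 3) in WT and 47.1% ± 18.5 (SD, n = 5) in DKOITD marrow (exact permutation p = 0.0714, adjusted p = 0.235). The share was 35.7% in DKOITD48, 32.1% in DKOITD53e and 35.7% in DKOITD83, the 3 mice with small territories, 57.1% in DKOITD185 and 75% in DKOITD52, and 64.3% to 85.7% in WT.

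The other lists had adjusted p from 0.235 to 0.821 for H3K27ac. B lineage genes were marked at 36.7% ± 20.2 (SD, n = 3) in WT and 18% ± 9.08 (SD, n = 5) in DKOITD marrow. T lineage genes were marked at 12.2% ± 6.94 (SD, n = 3) and 8.67% ± 5.06 (SD, n = 5). Housekeeping genes were marked at 95.0% and 90.0% ± 7.07 (SD, n = 5). The 54 developmental transcription factors, classic Polycomb targets, were marked by H3K27me3 at 100% in WT and 91.1% ± 8.82 (SD, n = 5) in DKOITD marrow, and by H3K27ac in no mouse. DKOITD52 and DKOITD185 had H3K27me3 at 100% of them, like WT, and DKOITD48, DKOITD53e and DKOITD83 at 87.0%, 79.6% and 88.9%. HoxA genes, homeobox regulators of progenitors, were marked by H3K27me3 at 90.9% in each WT mouse and 67.3% ± 19.9 (SD, n = 5) in DKOITD marrow (45.5% in DKOITD48 and DKOITD83, 81.8% in the other 3), with an adjusted p of 0.365. The Polycomb and H3K27 demethylase list, at 27.3% ± 9.09 (SD, n = 3) and 11.8% ± 8.26 (SD, n = 5), had the smallest p for H3K27me3 (exact permutation p = 0.0357, adjusted p = 0.308). It too was lowest in DKOITD48 and DKOITD53e, at 4.55% each, and DKOITD83, at 9.09%. By camera no list passed for H3K27me3, with an adjusted p of 0.984 for each with an estimated correlation.

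**Figure D3:**
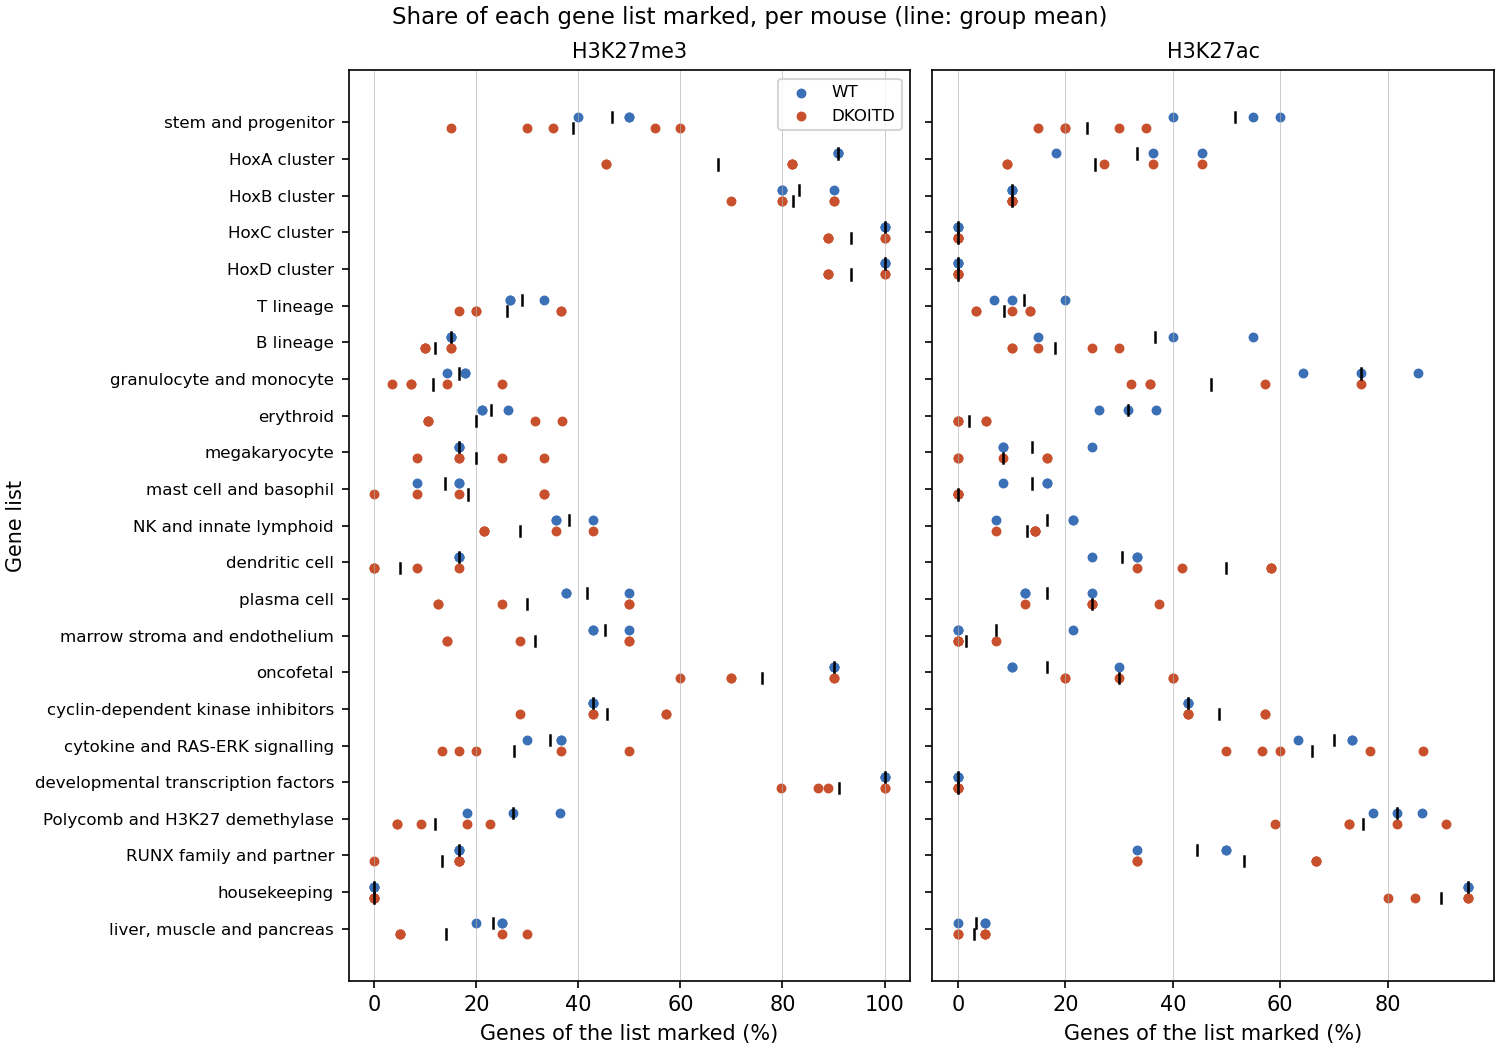
Percent of each gene list marked (horizontal axis) in every mouse, with H3K27me3 left and H3K27ac right, WT in blue, DKOITD in orange and short lines for group means (points of equal value overlap). For H3K27ac the erythroid means are 31.6% in WT and 2.11% in DKOITD, and the dendritic cell means 30.6% and 50%.

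Of all genes, 39.8% ± 1.39 (SD, n = 3) in WT and 38.3% ± 4.20 (SD, n = 5) in DKOITD marrow had H3K27ac only. H3K27me3 only was found at 15.9% ± 1.58 (SD, n = 3) and 10.3% ± 6.12 (SD, n = 5), both marks at 2.36% ± 0.892 (SD, n = 3) and 1.49% ± 1.52 (SD, n = 5), and neither mark at 41.9% ± 3.77 (SD, n = 3) and 49.9% ± 11.1 (SD, n = 5). The better covered gene end was taken for each mark, so a gene with both marks can carry them at opposite ends. No state differed beyond the spread between mice (exact permutation, adjusted p 0.429 to 0.643). The ratio of H3K27me3 to H3K27ac territory was 0.922 ± 0.0981 (SD, n = 3) in WT and 0.948 ± 0.605 (SD, n = 5) in DKOITD marrow (exact permutation p = 0.929). H3K27ac peak sets were more alike within genotypes than between them by a Jaccard index of 0.0937 (one-sided exact permutation p = 0.0357), and H3K27me3 sets by 0.0349 (p = 0.214 in the same exact test). For mouse H3K27me3 replicate similarity the mean index was 0.455 within WT, 0.278 within DKOITD marrow and 0.284 between genotypes. The DKOITD mean pooled unlike pairs. The index was 0.469 to 0.548 among DKOITD48, DKOITD53e and DKOITD83, and 0.487 between DKOITD52 and DKOITD185. Pairs across these groups had 0.0769 to 0.169, where unequal territories also limit the index. The call for mouse H3K27ac replicate similarity was lost with peaks of −log10 q at least 5, where p was 0.143. In the same exact test it was also lost without WT1, WT2 or WT3 (p = 0.0952 each), DKOITD48 (p = 0.114), DKOITD52 (p = 0.0571) or DKOITD185 (p = 0.0571). The difference itself was then 0.0625 (without WT1) to 0.130 (without DKOITD185), against 0.0937 with all mice. Fewer assignments remain without a mouse, which raises the smallest possible p.

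In the cell lines, H3K27me3 peaks were plentiful in Jurkat and nearly missing in Loucy. They covered 11.6 and 6.80 Mb in the Jurkat libraries and 0.258 and 0.227 Mb in the Loucy libraries, from 189 and 200 peaks. Between the lines the exact permutation p was 0.333, the smallest that 2 against 2 libraries allow. The contrast lay in peaks with a −log10 q under 5, which were nearly all of those in Jurkat. Peaks of −log10 q at least 5 numbered 24 and 23 in the Jurkat libraries and 70 and 86 in the Loucy libraries. With these few peaks the difference in human H3K27me3 territory changed sign, to 0.0673 Mb more in Loucy. In Loucy, 21.4% and 21.3% of this territory lay on contigs outside the main chromosomes. Loucy libraries held 5974153 and 3900279 fragments and Jurkat libraries 9209392 and 12261421. Peaks held 1.77% and 1.94% of them in Loucy and 5.04% and 2.93% in Jurkat. The Jurkat replicates overlapped poorly, with a Jaccard index of 0.139, against 0.660 in Loucy. Of the regions, 3241 were held by both Jurkat and neither Loucy library and 70 the reverse. With the stricter peaks these counts were 4 and 40. For human H3K27me3 switched regions, lost in Loucy, the count was 9907 without Jurkat1 and 16485 without Jurkat2. The longest of the 3241 on a main chromosome (hg38 chromosome 1, 18634610 to 18648310) spanned 13.7 kb.

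H3K27ac covered similar lengths in the lines, 48.9 and 45.3 Mb in Jurkat and 44.0 and 64.2 Mb in Loucy (exact permutation p = 1.0). The difference in human H3K27ac territory changed sign without Loucy2, to -3.09 Mb, and with peaks of −log10 q at least 5, to -6.27 Mb. Positions overlapped less between than within lines. The mean Jaccard index between lines was 0.288, against 0.673 within Jurkat and 0.529 within Loucy. Of 61190 regions, 7636 were held by both Jurkat libraries and neither Loucy library, 8263 the reverse, and 13502 by all 4. For human H3K27ac switched regions, lost in Loucy, the count was 14100 without Jurkat2. For human H3K27ac switched regions, gained, it was 21686 without Loucy1 and 12665 without Loucy2, and with the stricter peaks the counts were 3923 and 1185. The longest Loucy region (hg38 chromosome 17, 48560480 to 48648572) spanned 88.1 kb, and the longest Jurkat region (chromosome 2, 239243729 to 239282168) spanned 38.4 kb. The stretches with H3K27me3 in both Jurkat libraries, 2.24 Mb, lay under H3K27ac for 1.68% and 1.57% of their length in Jurkat and 7.60% and 8.71% in Loucy. Nothing in the labels says that replicates of a line came from separate cultures, so their spread may be technical.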

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

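The tests of depth, enrichment, sex and the 7 granule genes, and those of the gene counts against other splits, were chosen after the results were seen. Of 55 groups of 5 DKOITD values, 3 had a mouse flagged by an outlier test. In each of these the other mice had equal values, so any difference would be flagged, however small. These flags therefore carry no weight. H3K27me3 marked 0% of the RUNX family and partner list in DKOITD83. H3K27ac marked 7.14% of the NK and innate lymphoid list in DKOITD83, and 7.14% of the marrow stroma and endothelium list in DKOITD52.

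The territories of DKOITD48, DKOITD53e and DKOITD83 were small for both marks. Sequencing depth is argued against: the fewest H3K27me3 fragments of the 3 mice were 1.21 times those of WT1, whose territory was 27.3 Mb, and DKOITD53e and DKOITD83 had more fragments than any WT mouse. Weaker enrichment in both immunoprecipitations is left open: the highest percent of H3K27ac fragments in peaks of the 3 mice lay below the lowest of the other 5, at -2.91 percentage points, but that percent falls with the territory itself and decides nothing. The percent of fragments removed as duplicates was highest in the same 3 mice. For H3K27me3 it was 12.5% to 13.5%, against 7.54% to 10.7% in the other 5. For H3K27ac it was 10.8% to 11.2%, against 5.35% to 9.64%. This difference was not tested as a cause. No biological explanation was tested, as no label separates these mice from DKOITD52 and DKOITD185.

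H3K27ac at the granulocyte and monocyte list was found at 75% of genes in WT and 47.1% in DKOITD marrow, but at 32.1% to 35.7% in DKOITD48, DKOITD53e and DKOITD83, which had the small territories, and at 57.1% in DKOITD185 and 75% in DKOITD52. Kit selection of WT marrow alone would lower, not raise, the share of late neutrophils in WT. The granulocyte and monocyte list also covers other cells, so that expectation does not apply to it as a whole. It differed by -25.5 percentage points relative to all genes, with an exact permutation p of 0.0714. Selection went with genotype in every mouse, so it cannot be told apart from genotype here at any p. A set of 7 granule genes differed by -64.8 points, but it was written after Camp and S100a8 had been seen among the lost genes and decides nothing. Different numbers of peaks may account for part of the pattern: at equal peak numbers the list differed by -13.1 points (exact permutation p = 0.107). Of all genes that lost H3K27ac, on this list or not, 12.9% still switched then. But 86 genes met the rule of loss, against 101 before, and the trimming removed WT peaks as well. That 12.9% therefore does not show that peak number made the losses.

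A larger part of the H3K27me3 territory lay on chromosome X in WT mice, 2.25% to 5.15%, than in DKOITD mice, 0.451% to 1.32%. The sex of the mice may explain it: the lowest share among the 4 mice without H3K27ac at Y-linked genes exceeded the highest among the 4 with it by 0.355 points. Peak number may contribute, since at equal peak numbers the lowest WT share lay below the highest DKOITD share, at -0.819 points, and the separation by Y-linked marks was not kept either, with WT at 0.124% to 0.208% against 0.668% in DKOITD48 and 0.451% in DKOITD53e, which had such marks. Against it as the whole cause, DKOITD185 and DKOITD52, with 25557 and 15529 peaks, had shares of 0.841% and 0.964%, and WT2, with 7956 peaks, had 2.25%. Genotype stays open as well, because only DKOITD83 had no such Y-linked marks.

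Against other splits of the 8 mice, under 0.05 of the splits reached the H3K27ac losses, limma's higher H3K27ac genes and the exchange of marks. The smallest share possible is 1 of 56. Several counts were compared without adjustment, and those of switched genes were tested after they were seen. These shares therefore do not exclude chance. For H3K27ac, 1 of 56 splits gave as many lost regions as the 1117 found (highest other 498), and 2 gave as many lost genes as the 101 found (highest other 103). For the 11 genes that exchanged marks, 1 split gave as many and the highest other was 0. With peaks of −log10 q at least 5 the exchange was found at 0 genes, but no gene lost H3K27me3 at that setting. limma's 186 lower H3K27ac genes were reached by 1 split (highest other 101). Its 61 higher genes were reached by 2, but the other split gave 3451.

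For the other counts, at least 0.05 of the splits gave as many. H3K27ac gains were reached by 3 splits for the 82 genes (highest other 270) and 3 for the 162 regions (highest other 1003). H3K27me3 losses were reached by 3 splits for the 67 genes (highest other 135) and 5 for the 130 regions (highest other 734). H3K27me3 gains were reached by 9 splits for the 2 genes (highest other 1156) and 8 for the 3 regions (highest other 2124). limma's counts of 0 for H3K27me3 could not be tested this way, since every split reaches 0. The highest others were 104 lower and 2509 higher. At an unadjusted p under 0.05 there were 4 lists for H3K27ac, reached by 5 splits (highest other 5), and 1 for H3K27me3, reached by 24 (highest other 6). The split of DKOITD48, DKOITD53e and DKOITD83 from the other mice gave the highest counts of gains. Examples are 270 against 82 genes for H3K27ac and 1156 against 2 for H3K27me3. This points to a structure of the libraries other than genotype.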

How the results depend on the processing

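The settings that leave out 3 DKOITD mice, chromosomes X and Y or shared stretches, the whole-gene windows, camera, the unadjusted list threshold, the exchange of marks with stricter peaks and the human region counts were chosen after seeing the data. The cause of the changes given here was not tested. Weak or narrow peaks are what low depth misses first. The stricter setting left 95 to 814 H3K27me3 peaks per WT mouse, 184 to 2015 per DKOITD mouse, 24 and 23 in Jurkat and 70 and 86 in Loucy. H3K27me3 results at that setting therefore rest on few peaks, and few losses could be counted there. With peaks of −log10 q at least 5 the difference was 3.88 Mb for mouse H3K27me3 territory, 0.0673 Mb for human H3K27me3 territory and -6.27 Mb for human H3K27ac territory. Without each library in turn these ranged from -9.94 to -0.619, from -11.4 to -6.56 and from -3.09 (without Loucy2) to 17.1 Mb, and mouse H3K27ac territory from -11.1 to -4.62 Mb. The last, -8.21 Mb in the report, was -3 Mb with the stricter peaks and -3.70 Mb at equal peak numbers. For mouse H3K27ac replicate similarity the value was 0.0541 with the stricter peaks (p = 0.143, exact permutation) and 0.0625 to 0.130 without each library, where, of these, the call held only without DKOITD53e or DKOITD83. For mouse H3K27me3 replicate similarity, 0.0349 in the report, it was 0.0936 with the stricter peaks and from 0.00282 (without WT1) to 0.113 (without DKOITD52) without each library. Promoter states, named as planned, were counted at both gene ends. For promoter states, H3K27me3 only differed by 1.86 points with the stricter peaks; for promoter states, both marks by 0.0807; for promoter states, neither mark by -0.366; and for promoter states, H3K27ac only by 0.710 at equal peak numbers.

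For mouse H3K27me3 switched genes, lost (67), the counts were 0 with the stricter peaks, 37 at equal peak numbers, 218 by non-overlap of covered length (chance gives 1.79% of genes), 0 by limma at an adjusted and 423 at an unadjusted p, and 67 to 189 without each library (189 without WT2, 182 without DKOITD52). For mouse H3K27me3 switched genes, gained (2), they were 16 with the stricter peaks, 22 at equal peak numbers, 0 at 1000 bp, 4 with 2.5 kb windows, 0 by limma at an adjusted and 7 at an unadjusted p, 198 without DKOITD48, DKOITD53e and DKOITD83, and 2 to 4 without each library (4 without DKOITD83). For mouse H3K27ac switched genes, lost (101), they were 28 with the stricter peaks, 162 at 1000 bp, 1218 by non-overlap, 186 by limma at an adjusted and 1743 at an unadjusted p, and 102 to 178 without each library (178 without WT2, 165 without DKOITD52). For mouse H3K27ac switched genes, gained (82), they were 15 at 1000 bp, 183 at equal peak numbers, 208 by non-overlap, 61 by limma at an adjusted and 309 at an unadjusted p, 373 without the 3 mice, and 82 to 130 without each library (129 without WT1, 130 without DKOITD53e). Leaving out a library relaxes the rule, so these gene counts cannot fall.

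For mouse H3K27me3 switched regions, lost (130), the counts were 0 with the stricter peaks, 57 at equal peak numbers and 130 to 515 without each library (515 without WT2, 230 without WT3, 290 without DKOITD52). For mouse H3K27me3 switched regions, gained (3), they were 16 with the stricter peaks, 19 at equal peak numbers, 6 at 1 bp, 0 at 50%, 1939 without the 3 mice and 3 to 8 without each library (8 without DKOITD53e, 5 without DKOITD83). For mouse H3K27ac switched regions, lost (1117), they were 83 with the stricter peaks, 358 at equal peak numbers and 1120 to 2329 without each library (2329 without WT2). For mouse H3K27ac switched regions, gained (162), they were 84 with the stricter peaks, 291 at equal peak numbers, 72 at 50%, 1865 without the 3 mice and 162 to 315 without each library (244 without WT1 or DKOITD83, 315 without DKOITD53e). For human H3K27me3 switched regions, lost in Loucy (3241), they were 4 with the stricter peaks, 1584 at 50%, 20 at equal peak numbers and 3241 to 16485 without each library (9907 without Jurkat1, 16485 without Jurkat2). For human H3K27me3 switched regions, gained (70), it was 40 with the stricter peaks. For human H3K27ac switched regions, lost (7636), they were 3923 with the stricter peaks and 7934 to 14100 without each library (14100 without Jurkat2). For human H3K27ac switched regions, gained (8263), they were 1185 with the stricter peaks and 8700 to 21686 without each library (21686 without Loucy1, 12665 without Loucy2).

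In the permutation test of list shares no list passed after adjustment. At an unadjusted p there were 4 for H3K27ac and 1 for H3K27me3, and camera with its preset correlation called 3 for H3K27ac. For mouse reciprocal switches, H3K27me3 lost and H3K27ac gained, the count was 2 at equal peak numbers (Fisher's exact p = 0.0318) and 0 with the stricter peaks. Of 38 calls at named genes, the stricter peaks ended 34, a minimum of 1000 bp 26, equal peak numbers 25, the whole-gene window 12, 2.5 kb windows 8 and a minimum of 1 bp 1. The settings without libraries and by non-overlap cannot end such a call. Leaving out libraries for lists (no adjusted p could pass), the most upstream start site and the mouse to human overlap were not run. Paired by replicate number, as a replicate block, the Loucy minus Jurkat territory differences were -8.97 Mb (p = 0.5, exact sign flips) for H3K27me3 and 7.03 Mb (p = 1.0, exact sign flips) for H3K27ac. The numbers have no stated link between lines, and the mouse genotypes share none.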

Other observations

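The test of X-linked genes was chosen after the X shares were seen. Of 21883 genes, 876 carried H3K27me3 in all 8 mice and 5662 in at least 1. The 806 regions held in every mouse spanned 9.42 Mb, and the longest was 147215 bp. Of these regions, 86.7% touched a gene-end window. In contrast 71.4% of the 41384 H3K27me3 regions were held by a single mouse, and only 5.77% of those touched such a window. Their median length was 362 bp, against 8444.5 bp for regions held in every mouse. Longer regions touch a window more often by length alone, so these percents do not compare location. HoxC and HoxD genes were marked by H3K27me3 at 93.3% ± 6.09 (SD, n = 5) for either list in DKOITD marrow, and at 100% in WT. DKOITD52 and DKOITD185 were at 100% as well, and DKOITD48, DKOITD53e and DKOITD83 at 88.9%.

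At Kit, on which WT marrow was selected, H3K27me3 was found in 0 of 3 WT and 3 of 5 DKOITD mice. H3K27ac was found there in 3 of 3 and 0 of 5. At Spry2 and Pip5k1b, H3K27me3 was found in 0 of 3 WT and 4 of 5 DKOITD mice, and H3K27ac in 3 of 3 and 2 of 5. X-linked genes made up 3 of the 67 that lost H3K27me3 (Ddx3x, Magee1 and Fgd1, named after their values were seen) and 72 of the 3161 marked in all WT mice (Fisher's exact test, p = 0.195).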
